A study of Cloeon viridulum with 15 samples.

How the data were processed

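RNA of whole mayflies (Cloeon viridulum) was sequenced from young larvae, mature larvae, subimagoes, imagoes and a mixture of these stages, with 3 libraries per group and 15 in all. Per the labels, larvae were collected in the field and reared indoors at 22 ± 1 °C and 60% relative humidity with 16 h of light and 8 h of dark. Each library held RNA of several animals, 10 young larvae, or 3 males and 3 females of a later stage, or 11 animals for the mixture. Per the labels' protocols, libraries were made from 1 µg of RNA with the TruSeq kit and read as 125 bp pairs on an Illumina HiSeq instrument. Low-quality and ribosomal RNA reads were removed, and the reads were assembled without a genome by CLC Genomics Workbench followed by CAP3, into sequences called unigenes. The read mapper and the counting settings are not given in the sources used here, nor is the strand setting. The submitters' processing notes name DESeq, without a version.

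The deposited table holds, for each unigene and library, the counts of reads that the authors assigned to it, and RPKM values, which are reads scaled by unigene length and library total. Each deposited RPKM value equals the count divided by the unigene length and the library's total count, with a largest relative difference of 3.42e-07. Every column of counts or RPKM values of a library matched 1 library of the labels by the number in its description. A further column holds the mean RPKM over all libraries. The table lists 91881 unigenes with a median length of 487 bp. It pairs 31014 of them (33.8%) with a best protein hit, from which protein names were taken, and leaves 60867 without one. The best hit's species code was used to sort unigenes into arthropod, other animal, and protist or fungal hits. No reference genome was used, so unigenes have no chromosome position. Several unigenes can be pieces of 1 gene or near copies of each other, and how reads were split between them is not known, so values of single members of a gene family are uncertain.

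Only the counts were tested. edgeR 4.0.16 with limma 3.58.1 in R 4.3.3 fitted the quasi-likelihood model (glmQLFit and glmQLFTest, robust) to all 15 libraries and 5 groups, which share 1 estimate of the spread. TMM scaling and the filterByExpr filter were used, which left 34131 unigenes. Adjusted p-values are Benjamini-Hochberg values over these unigenes, and a unigene was called at an adjusted p under 0.05. Levels are CPM, counts scaled by library size, after TMM scaling, given as mean ± SD over 3 libraries, and log2 changes are given ± SE from the model. The labels call the 3 libraries of a group biological replicates, each a pool of animals. The p-values rest on the spread between libraries within all 5 groups, including the mixture and mature larva replicate 1, which lay apart. Totals ran from 36550269 to 74837923 reads per library. A count of 0 over the 3 young larva libraries allows up to 3 reads, or 0.0189 CPM. Folds against a group without a read were computed against this floor over the group, and with 1 to 3 reads the ratio is given with its exact 95% Poisson interval. Such floors and intervals cover counting error only.

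The comparisons, the tests, 23 gene lists and the rule for naming genes were fixed before the data were examined. The comparisons are the 3 successive stage transitions, each stage against the mixture, and the unigenes higher or lower in the subimago than in both neighbouring stages. The gene lists were formed by words in the annotation: cuticular proteins; chitin synthesis, turnover and tanning; ecdysteroid synthesis and response; juvenile hormone synthesis and response; moulting and eclosion neuropeptides; muscle structure; wing patterning and growth; digestive enzymes; detoxification enzymes; photoreception; chemoreception; oxidative phosphorylation; glycolysis and the tricarboxylic acid cycle; fatty acid synthesis and oxidation. The remaining lists were ion transport and osmoregulation, haemocyanin, hexamerin and storage proteins, egg yolk, eggshell and oogenesis, sperm and axoneme, DNA replication and cell division, cytosolic ribosomal proteins, heat shock proteins and chaperones, immune response, and algal and plant genes as gut content. Counts of list members cover those with an animal best hit, from arthropods or other animals. Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists and transitions. The test covers the whole list, protist hits included, and lists need at least 5 tested unigenes. With the correlation estimated for each list, no list was called at any transition, against 13, 9 and 6 lists of 22 at the preset value, and each such value stands beside its list. limma's fry, which tests each list on its own, called 18, 7 and 6.

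For each transition the rule named the 8 largest rises and the 8 largest falls among called unigenes whose 3 libraries of 1 stage all lay above those of the other. It further required a mean of at least 10 CPM in the higher stage and a named protein, and took 1 unigene per annotation text. Groups of 3 against 3 are separated by chance in 10% of unigenes. From each list it took up to 3 members with the smallest adjusted p and at least 1 CPM, and for the 2 hormone lists any member a sentence needed. Unigenes named outside this rule are said to be so.

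The alternatives were fits to only the libraries compared, the replicate number as a block, DESeq2's size factors, library totals alone, no filter, a filter of 10 CPM in 3 libraries, a fold of at least 2, DESeq2 1.42.0, leaving out each library, and other list tests. Further alternatives were chosen after seeing the data. These were scaling on arthropod-hit unigenes, arthropod-hit unigenes alone, leaving out the unigene First_Contig81 with the short unigenes that follow it, counts of the lists and unigenes without mature larva replicate 1, and lists limited to animal hits. The procedure was tested on simulated counts drawn from the real means and library sizes, with 100 unigenes changed 2-fold and 100 changed 4-fold. Between mature and young larvae it recovered 3% of the former and 53% of the latter among 32213 unigenes. The values were 7% and 43% for subimago against mature larva (32178 unigenes) and 4% and 34% for imago against subimago (32333 unigenes). Far fewer unigenes were changed there than were called in the data, which makes the adjusted threshold stricter. These rates therefore do not measure recovery in the real comparisons.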

Results

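Cloeon viridulum is a mayfly, a member of the insect order whose animals moult again after they have gained working wings. The aquatic larva gives rise to a winged subimago, which moults to the imago, the reproductive adult, and neither winged stage feeds. The series compares whole bodies at 4 stages of this life cycle, called prometabola, together with a mixture of the stages. There were 3 libraries per group. A young larva library pooled 10 animals, a library of a later stage pooled 3 males and 3 females, and a mixture library pooled 5 young larvae with 2 animals of each later stage. Reads had been assigned to 91881 unigenes of 300 to 22030 bp, and 34131 unigenes were tested, of which 11940 had an arthropod best hit. Totals were 36550269, 44206541 and 48798785 reads for the young larvae and 74837923, 46976259 and 49983472 for the mature larvae. They ran from 42167085 to 43196419 for the subimagoes, 42017488 to 46642654 for the imagoes and 37396984 to 48915598 for the mixture.

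Mature larva replicate 1 lay apart from the other mature larvae, and young larva replicate 2 from the other young larvae. On the first principal component of the arthropod-hit unigenes, young larva replicates 1, 2 and 3 lay at 249, 198.3 and 245, mature larva replicates 2 and 3 at -39.9 and -57.1, and mature larva replicate 1 at 119. Replicate 1 also held reads of 75863 unigenes, against 46421 and 47983 in the other mature larvae and 65920 to 72586 in the young larvae. Unigenes with a protist or fungal best hit took 8.00%, 1.74% and 5.05% of the reads of the young larvae, 2.45% of mature larva replicate 1 and 0.193% to 0.488% of every other library. Other-animal hits took 8.35%, 2.75% and 5.62%, then 3.41%, and 0.976% to 2.77% of every other library. Their median log2 change was -1.84 from young to mature larva and -2.56 to the subimago, against 0.216 and 0.0904 for arthropod hits. Whether other-animal hits are mayfly transcripts was not tested, and counts of list members over animal hits include them. A set of 1244 unigenes had at least 10 reads in every young larva library and none in the other 8 mature larva, subimago and imago libraries. Of the set, 642 had a protist or fungal best hit and 63 an arthropod hit. In mature larva replicate 1, 1239 of the 1244 had reads. Their median level there was 27.2%, 70.9% and 29.6% of that in young larva replicates 1, 2 and 3. Counts of list members and of called unigenes that use the mature larvae at a transition are therefore also given without this library. The unigene First_Contig81, without a protein hit, took 34.3% of the reads of mixture replicate 3, 21.5% of subimago replicate 3 and 18.5% of imago replicate 2.

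**Figure D1:**
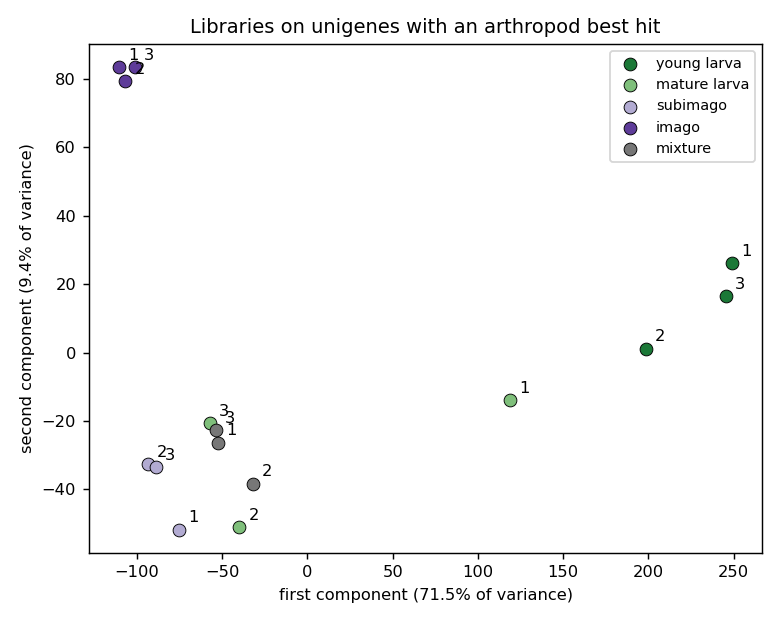
Principal components of log2 CPM of the arthropod-hit unigenes, with the first component (71.5% of the variance) on the x axis and the second (9.38%) on the y axis; each point is 1 library, coloured by group and numbered by replicate. Young larvae lie at 198.3 to 249 on the first component, mature larva replicate 1 lies at 119 between them and the other libraries, and the imagoes lie at 79.4 to 83.5 on the second.

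**Figure D2:**
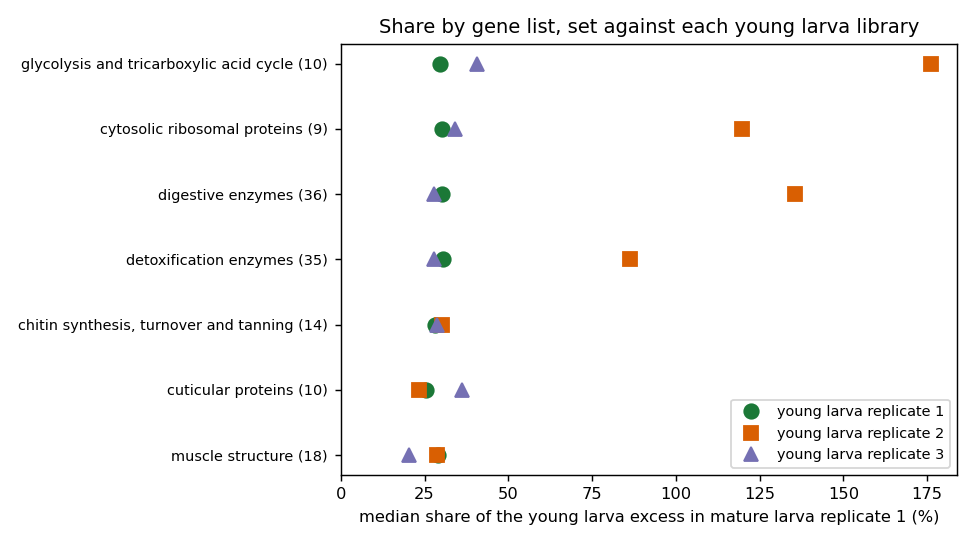
Level of young larva genes in mature larva replicate 1, as the median percent of each gene list's excess in a young larva library (x axis), with 1 point per list and per young larva replicate, for the 7 lists with enough such unigenes (their number in brackets). Set against young larva replicate 1 the lists lie between 25.4% and 30.5%, against replicate 2 between 23.4% and 176%, and against replicate 3 between 20.4% and 40.6%.

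The comparison of mature with young larvae covers growth within the aquatic larval period. Genes of egg formation had the highest median log2 change of the fixed lists. Vitellogenin (13_Contig_814), the precursor of egg yolk, rose from 0.164 ± 0.0713 to 197 ± 89.8 CPM (log2 change 10.18 ± 0.51, adjusted p = 9.85e-09, n = 3 per stage). Bicaudal C (13_Contig_854), an RNA-binding protein of oogenesis, rose from 0.501 ± 0.142 to 528 ± 197 CPM (log2 change 10.03 ± 0.46). The vitellogenin receptor (13_Contig_5313), which takes yolk into the oocyte, had no read in the young larvae and 44.3 ± 10.3 CPM in the mature larvae, at least 2346-fold more. Of 11 egg yolk, eggshell and oogenesis unigenes, 7 rose and 2 fell (7 and 2 adjusted over the list alone). Their median log2 change was 5.21 (adjusted p = 0.000821 by camera and adjusted p = 0.228 with an estimated correlation), and without mature larva replicate 1 the counts were again 7 and 2.

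More genes of cell division rose than fell. Of 41 DNA replication and cell division unigenes, 30 rose and 11 did not pass (adjusted p = 0.0308 by camera and adjusted p = 0.718 with an estimated correlation; 30 rose adjusted over the list alone), with a median log2 change of 1.10. With library totals alone 14 rose, and without mature larva replicate 1 the list had 30 that rose and 8 that fell of 42. Among them, the replication licensing factor MCM3 (13_Contig_2006) rose by 2.42 ± 0.18 and the mitotic activator CDC20 (13_Contig_890) by 3.69 ± 0.24 on the log2 scale. Of 68 heat shock proteins and chaperones, 29 rose and 4 fell (29 and 5 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.905 by camera, upwards, with a median log2 change of 0.38 over animal hits and a mean of -0.09 over the whole list). Under library totals 12 rose and 8 fell, with a median of -0.19 over animal hits, and without mature larva replicate 1, 32 rose and 13 fell. Heat shock protein 70 (13_Contig_219) rose from 6.74 ± 0.664 to 450.4 ± 189 CPM (log2 change 6.06 ± 0.27) and a small heat shock protein (13_Contig_1332) by 5.84 ± 0.28. Linker histone H1 (13_Contig_411), which packs chromatin, had no read in the young larvae and 221 ± 22.3 CPM in the mature larvae, at least 11694.5-fold more. A sperm-tail protein (13_Contig_1196), the poly(ADP-ribose) polymerase tankyrase (13_Contig_3233), a bromodomain protein (13_Contig_1505) and an ankyrin repeat protein (13_Contig_994) had no young larva read either, at folds of at least 2782, 4073, 4366 and 12869.5. A BTB/POZ protein (13_Contig_3167) had 2 young larva reads, for a ratio of 36364 (95% interval 10066.7 to 300271).

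More muscle, glycolytic and ribosomal protein genes fell than rose. Of 47 muscle structure unigenes, 30 fell and 1 rose (1 and 33 adjusted over the list alone). The median log2 change was -2.05 (adjusted p = 1.31e-06 by camera and adjusted p = 0.638 with an estimated correlation), and without mature larva replicate 1, 35 of 50 fell and 2 rose. Sarcomeric alpha-actinin (13_Contig_4390), which anchors actin filaments at the Z disc, fell from 986 ± 146 to 232 ± 118 CPM (log2 change -2.09 ± 0.28, adjusted p = 6.59e-05). Tropomyosin 1 (13_Contig_4301) fell by 1.66 ± 0.24 on the log2 scale, while troponin C isoform 1 (13_Contig_6848), a calcium sensor of the sarcomere, rose from 0.695 ± 0.142 to 44.6 ± 20.1 CPM. Of 55 glycolysis and tricarboxylic acid cycle unigenes, 22 fell and 5 rose (7 and 22 adjusted over the list alone; adjusted p = 8.14e-06 by camera and adjusted p = 0.647 with an estimated correlation), and without mature larva replicate 1, 32 of 60 fell and 8 rose. Enolase (13_Contig_5673) fell from 589.9 ± 133 to 160.4 ± 59.3 CPM and triosephosphate isomerase (13_Contig_11201) from 224 ± 47.3 to 62.5 ± 21.5 CPM. Of 106 cytosolic ribosomal protein unigenes, 62 fell and 2 rose (2 and 62 adjusted over the list alone; adjusted p = 8.23e-15 by camera and adjusted p = 0.638 with an estimated correlation). An example is 40S protein S3a (13_Contig_3022, log2 change -1.19 ± 0.10), and 89 of 112 fell and 2 rose without mature larva replicate 1. Of 71 oxidative phosphorylation unigenes, 13 rose and 14 fell (13 and 15 adjusted over the list alone; adjusted p = 0.00188 by camera and adjusted p = 0.718 with an estimated correlation, downwards). The counts were 10 and 21 with DESeq2's size factors, 9 and 27 with library totals and 10 and 22 with arthropod scaling. On its animal hits alone camera gave an adjusted p = 0.185, and without mature larva replicate 1, 16 rose and 23 fell of 75.

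Lists of feeding, defence and cuticle also had more falls than rises. Of 201 digestive enzyme unigenes, 51 fell and 28 rose (29 and 54 adjusted over the list alone; adjusted p = 3.00e-05 by camera and adjusted p = 0.647 with an estimated correlation). Without mature larva replicate 1, 116 of 208 fell and 30 rose. The members with the smallest adjusted p were serine proteases that rose, among them HTRA2 (13_Contig_1764), a protease of mitochondria rather than the gut, with a log2 change of 4.98 ± 0.22. Of 135 detoxification enzymes, 35 fell and 20 rose (20 and 39 adjusted over the list alone; adjusted p = 0.00125 by camera and adjusted p = 0.718 with an estimated correlation), and without that library 74 of 138 fell and 23 rose. Cytochrome P450 6BQ8 (13_Contig_4725) was among those that rose, from 1.83 ± 0.429 to 37.8 ± 11.1 CPM. Of 49 immune response unigenes, 11 fell and 3 rose (3 and 11 adjusted over the list alone; adjusted p = 0.000329 by camera and adjusted p = 0.638 with an estimated correlation). The Toll ligand spätzle (13_Contig_11064) had a log2 change of -1.62 ± 0.26, and without that library 23 of 51 fell and 3 rose. Of 9 haemocyanin, hexamerin and storage protein unigenes, 8 fell and 1 rose, as did 8 and 1 of 11 without that library (1 and 8 adjusted over the list alone; adjusted p = 0.0180 by camera and adjusted p = 0.647 with an estimated correlation). The lipid carrier apolipophorin (13_Contig_5361) fell from 117 ± 26.4 to 36.3 ± 10.6 CPM. Of 23 chemoreception unigenes, 9 fell and 1 rose (1 and 9 adjusted over the list alone; adjusted p = 0.00654 by camera and adjusted p = 0.638 with an estimated correlation), for example odorant binding protein 11 (13_Contig_26336, log2 change -1.80 ± 0.36). Without that library 11 of 24 fell and 1 rose. Of 32 cuticular proteins, 9 fell and 23 did not pass (7 fell adjusted over the list alone; adjusted p = 0.00172 by camera and adjusted p = 0.647 with an estimated correlation), and without that library 15 fell and 2 rose. At an unadjusted p under 0.05 the list had 1 higher and 18 lower. Of 67 chitin and tanning unigenes, 22 fell and 3 rose (4 and 23 adjusted over the list alone; adjusted p = 0.000401 by camera and adjusted p = 0.638 with an estimated correlation), and without that library 36 fell and 4 rose.

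The other lists were not called by camera between the larval stages, though some passed under other settings given below. Of 33 wing patterning and growth unigenes, 12 rose and 6 fell (13 and 6 adjusted over the list alone; adjusted p = 0.478), but 7 rose and 12 fell with library totals alone, 9 rose and 10 fell with DESeq2's size factors, and 10 rose and 10 fell with scaling on arthropod hits, and 14 of 34 rose and 5 fell without mature larva replicate 1. Hedgehog (13_Contig_2019), a patterning signal, rose from 9.00 ± 0.626 to 71.1 ± 20.4 CPM and the wing selector scalloped (13_Contig_1139) from 80.9 ± 2.39 to 187 ± 24.9 CPM. Of 33 photoreception unigenes, 12 rose and 7 fell (12 and 10 adjusted over the list alone; adjusted p = 0.991), with a median log2 change of -0.22 and a mean of 0.63, with library totals 9 rose and 12 fell, and without that library 12 and 8. A blue-sensitive opsin (13_Contig_20950) rose from 0.0271 ± 0.0171 to 2.78 ± 1.71 CPM, and the photoreceptor adhesion protein chaoptin (13_Contig_5239) fell from 58.1 ± 8.77 to 18.6 ± 3.65 CPM. Fatty acid synthesis and oxidation had 11 rises and 11 falls of 53 (11 and 11 adjusted over the list alone; adjusted p = 0.0647), 2 and 15 with library totals, 8 and 15 with DESeq2's size factors 7 and 15 with arthropod scaling, and 12 and 19 without that library. Ion transport and osmoregulation had 14 and 21 of 82 (15 and 23 adjusted over the list alone; adjusted p = 0.0578), 18 and 27 of 83 without that library. Sperm and axoneme had 7 and 2 of 22 (7 and 2 adjusted over the list alone; adjusted p = 0.264), 5 and 6 with library totals, and 8 and 3 without that library. The algal and plant list had 2 tested unigenes, too few for a test, of which 1 rose here and 2 rose in the subimago, as did 1 and 2 of 5 without that library.

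All 8 of the largest falls named were larger still without mature larva replicate 1. A lipase (13_Contig_18725) fell from 71.0 ± 67.9 to 2.16 ± 3.04 CPM (log2 change -5.02 ± 1.26, adjusted p = 0.00794), and its log2 change was -7.46 without replicate 1. The pigmentation protein yellow (13_Contig_11132) had log2 changes of -3.62 ± 1.26 and, without replicate 1, -7.78, and the RNA-degrading enzyme DsRNase 4 (13_Contig_33761) -3.86 ± 1.32 and -6.97. Over all settings the log2 change ran from -7.46 to -3.88 for the lipase, -7.78 to -3.02 for yellow and -6.97 to -3.19 for DsRNase 4, and their adjusted p reached 0.0802, 0.180 and 0.178. Luciferin 4-monooxygenase (13_Contig_35349) had log2 changes of -4.40 ± 1.42 and, without replicate 1, -8.64, and a firefly luciferase-like enzyme (13_Contig_28904) -4.36 ± 1.47 and -9.05. For Osiris 16 (13_Contig_16540) the values were -4.06 ± 1.22 and -5.91, for a serine hydrolase (13_Contig_16607) -3.79 ± 1.09 and -5.49, and for an RRP12-like protein (13_Contig_40475) -3.68 ± 1.21 and -7.23.

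edgeR called 8652 unigenes higher and 3322 lower in mature than in young larvae, and 4420 and 1898 of those with an arthropod hit. Without mature larva replicate 1 it called 9619 higher and 9932 lower among 38812, including 2723 protist hits that were lower. The share called higher was 72.3%, 51.8% with library totals alone, 61.1% with DESeq2, 58.7% among arthropod hits fitted on their own and 49.2% without that library. The median shift of single unigenes' log2 changes was -0.52 with library totals, -0.18 with DESeq2's size factors and -0.23 with scaling on arthropod hits. Here and below such shifts cover tested unigenes with a read in the groups compared. Camera's call of DNA replication was lost in 3 fits with a library left out (adjusted p = 0.285 without mature larva replicate 1) and with the stricter filter (adjusted p = 0.259). The calls of chemoreception, storage proteins and immune response were lost without young larva replicate 2, without mature larva replicate 2 and with the stricter filter (adjusted p = 0.0582, 0.0578 and 0.110). Fatty acid metabolism passed camera downwards without mature larva replicate 1 and without young larva replicate 2 (adjusted p = 0.0297 and 0.0262). With the stricter filter, camera called ion transport, juvenile hormone and fatty acid metabolism downwards (adjusted p = 0.00126, 0.0354 and 0.0354). Ion transport also passed downwards with 1 unigene per annotation text (adjusted p = 0.0494 by camera).

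**Figure D3:**
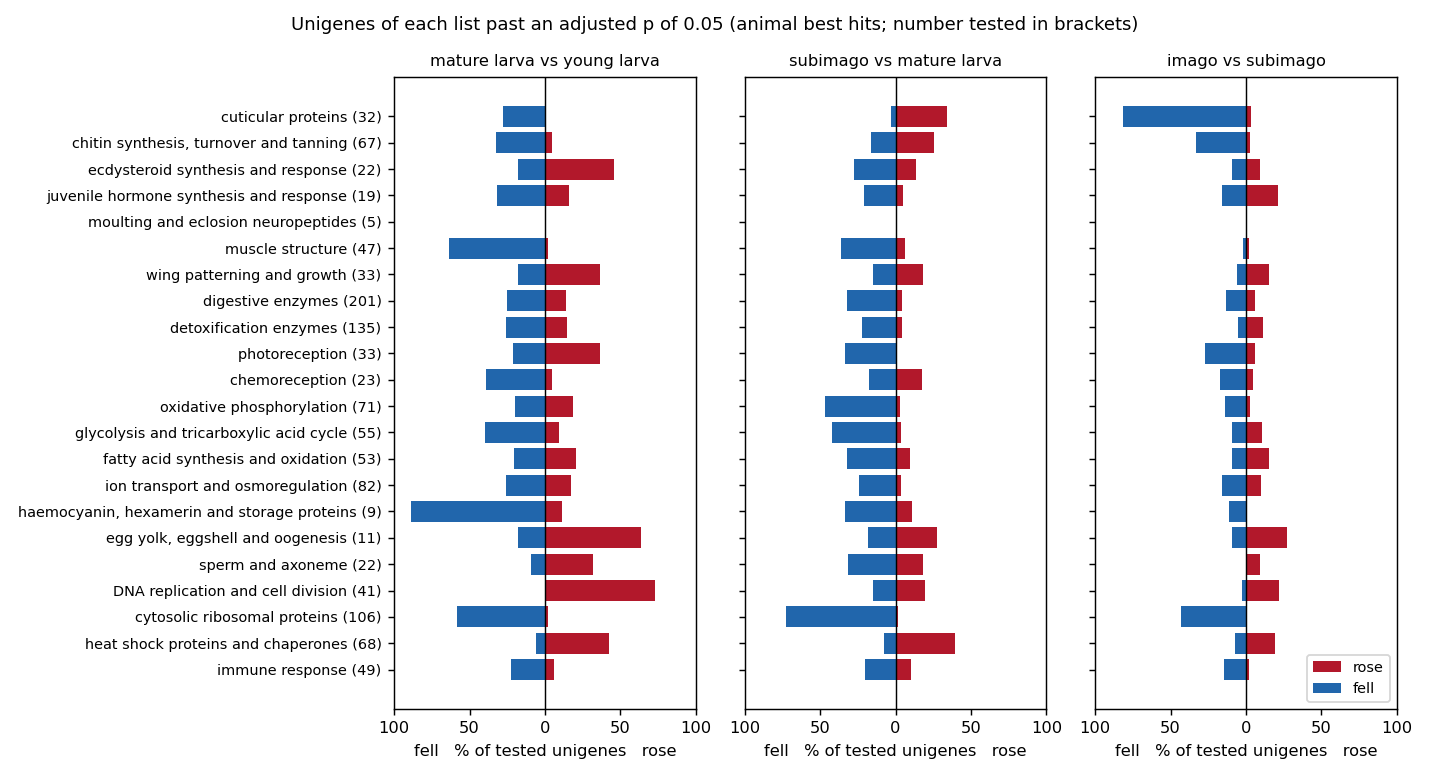
Percent of the tested animal-hit unigenes of each fixed list that rose (to the right of 0) or fell (to the left) at each stage transition, 1 panel per transition and 1 bar per list and direction. The cuticular protein bar points to rises from mature larva to subimago (11 of 32) and to falls from subimago to imago (26 of 32), and more ribosomal proteins fell than rose at every transition.

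The comparison of subimago with mature larva covers the passage from water to the winged stage. Cuticular proteins, which bind chitin in the body wall, made up 4 of the 8 largest rises named. A cuticle protein (13_Contig_2062) rose from 8.74 ± 4.23 to 919 ± 542 CPM (log2 change 6.72 ± 0.86, adjusted p = 0.00118, n = 3) and a pupal cuticle protein (13_Contig_826) from 22.1 ± 8.52 to 787 ± 499 CPM. ACP-20 (13_Contig_25170), named as adult-specific in its annotation, rose from 29.3 ± 28.3 to 969.8 ± 330.5 CPM. CPR67Bc (13_Contig_1860) rose from 12.9 ± 10.5 to 394 ± 72.0 CPM. Of 32 cuticular proteins, 11 rose and 1 fell (12 and 1 adjusted over the list alone). The list's median log2 change was 1.30 (adjusted p = 1.31e-06 by camera and adjusted p = 0.638 with an estimated correlation), and without mature larva replicate 1, 12 rose. Over all settings the log2 change of 13_Contig_2062 ran from 6.12 to 7.14 and that of 13_Contig_25170 from 4.68 to 6.14.

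Within the chitin and tanning list members went both ways. Of its 67 members, 17 rose and 11 fell (20 and 20 adjusted over the list alone). Their median log2 change was -0.83 although camera's direction was upwards (adjusted p = 0.413), and without mature larva replicate 1, 14 rose and 4 fell. Aromatic-L-amino-acid decarboxylase (13_Contig_1393), which makes dopamine for cuticle tanning, rose from 5.79 ± 1.96 to 53.8 ± 19.8 CPM and a chitinase (13_Contig_1449) from 97.8 ± 12.0 to 272 ± 63.5 CPM, while another chitinase (13_Contig_2278) fell from 9.11 ± 2.63 to 0.399 ± 0.195 CPM. Other large rises were the reductase-like protein msta (13_Contig_10973), from 1.30 ± 0.556 to 30.2 ± 3.30 CPM, protein takeout (13_Contig_8886), from 1.75 ± 0.957 to 47.2 ± 23.6 CPM, and a circadian clock-controlled protein (13_Contig_6108), from 2.33 ± 1.11 to 55.0 ± 33.3 CPM. The pigmentation protein yellow (13_Contig_1572) rose by 4.45 ± 0.78 on the log2 scale. Among digestive enzymes trypsin-7 (13_Contig_2864) rose from 23.3 ± 5.43 to 139 ± 20.1 CPM, whereas 64 of the list's 201 members fell and 9 rose (10 and 78 adjusted over the list alone; adjusted p = 0.00172 by camera and adjusted p = 0.718 with an estimated correlation). Without mature larva replicate 1, 18 of 208 fell and 8 rose. Chymotrypsin-like protein 2 (13_Contig_12906) fell from 6.02 ± 2.62 to 0.611 ± 0.237 CPM. Of 68 heat shock proteins and chaperones, 27 rose and 5 fell (30 and 6 adjusted over the list alone; adjusted p = 0.0386 by camera and adjusted p = 0.718 with an estimated correlation), such as chaperonin subunit alpha (13_Contig_4245, log2 change 0.86 ± 0.08). The mean log2 change over the whole list was -1.55 against a median of 0.00. Without that library 12 rose.

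Some visual genes fell. Opsin-1 (13_Contig_874), a light-sensing receptor, fell from 177 ± 136 to 5.25 ± 2.22 CPM (log2 change -5.07 ± 0.68, adjusted p = 0.00147) and rhodopsin (13_Contig_1132) from 1164 ± 409 to 233 ± 85.2 CPM. Of 33 photoreception unigenes, 11 fell and 22 did not pass (1 and 12 adjusted over the list alone; adjusted p = 0.0230 by camera and adjusted p = 0.638 with an estimated correlation), 8 fell without mature larva replicate 1, and the unadjusted counts were 2 higher and 15 lower.

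More muscle and energy genes fell than rose. Of 47 muscle structure unigenes, 17 fell and 3 rose (5 and 20 adjusted over the list alone; adjusted p = 0.0491 by camera and adjusted p = 0.748 with an estimated correlation), and without mature larva replicate 1, 11 of 50 fell and 2 rose. Muscle myosin heavy chain (Second_Contig9) fell from 2087 ± 1782 to 145 ± 39.8 CPM, a log2 change of -3.84 ± 0.65 that was -2.87 without that library, and flightin (13_Contig_7530), a thick-filament protein of flight muscle, fell from 265 ± 135 to 27.8 ± 10.8 CPM. Of 71 oxidative phosphorylation unigenes, 33 fell and 2 rose (2 and 42 adjusted over the list alone; adjusted p = 4.45e-06 by camera and adjusted p = 0.638 with an estimated correlation), and without that library 26 of 75 fell and 3 rose. ATP synthase subunit alpha (13_Contig_574) fell from 539 ± 144 to 176 ± 14.3 CPM, and a subunit of NADH dehydrogenase (13_Contig_2010) rose from 102 ± 29.3 to 557 ± 129.6 CPM. Of 55 glycolysis and tricarboxylic acid cycle unigenes, 23 fell and 2 rose (2 and 25 adjusted over the list alone; adjusted p = 0.0494 by camera and adjusted p = 0.768 with an estimated correlation), and 10 of 60 fell without that library. Of 106 ribosomal proteins, 77 fell and 2 rose (3 and 83 adjusted over the list alone; adjusted p = 4.81e-09 by camera and adjusted p = 0.718 with an estimated correlation), and 55 of 112 fell without that library. The 40S protein SA (13_Contig_12463) fell from 162 ± 15.5 to 40.8 ± 1.72 CPM. Of 82 ion transport unigenes, 20 fell and 3 rose (3 and 20 adjusted over the list alone; adjusted p = 0.104), and without that library 12 fell and 1 rose. Among them were 3 sodium pump alpha subunits (13_Contig_8480, 13_Contig_504 and 13_Contig_18657), at log2 changes of -1.13 ± 0.14, -1.20 ± 0.16 and -1.27 ± 0.17.

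In the remaining lists, 8 of 41 DNA replication unigenes rose and 6 fell (17 and 6 adjusted over the list alone; adjusted p = 0.0418 by camera and adjusted p = 0.718 with an estimated correlation, upwards), with a whole-list mean log2 change of -1.66 and median of 0.29. With scaling on arthropod hits 7 rose and 7 fell, and without mature larva replicate 1, 3 of 42 rose. Detoxification had 30 falls and 6 rises of 135 (7 and 33 adjusted over the list alone; adjusted p = 0.171), 8 and 3 of 138 without that library. Glutathione S-transferase sigma (13_Contig_8778) had 2 subimago reads, for a mature larva to subimago ratio of 1672 (95% interval 463 to 13806.5). Its log2 change was -10.48 ± 1.57, and -8.30 without replicate 1. Fatty acid metabolism had 17 falls and 5 rises of 53 (9 and 25 adjusted over the list alone; adjusted p = 0.104), 8 and 6 without that library, with a very long chain fatty acid elongase (13_Contig_4275) rising from 19.7 ± 3.03 to 97.1 ± 31.7 CPM. Immune response had 10 falls and 5 rises of 49 (5 and 12 adjusted over the list alone; adjusted p = 0.356), 5 and 5 with library totals, and 2 and 4 without that library. The receptor Toll (13_Contig_12415) fell from 20.8 ± 10.7 to 1.40 ± 0.493 CPM. Chemoreception had 4 rises and 4 falls of 23 (5 and 4 adjusted over the list alone; adjusted p = 0.264), 4 and 3 with library totals, 3 and 4 with arthropod scaling, and 4 and 2 of 24 without replicate 1, with an odorant receptor (13_Contig_2497) rising from 0.380 ± 0.149 to 2.73 ± 1.09 CPM. Sperm and axoneme had 7 falls and 4 rises of 22 (5 and 8 adjusted over the list alone; adjusted p = 0.264), 4 and 4 with library totals, and 2 falls without that library. Wing patterning had 6 rises and 5 falls of 33 (6 and 5 adjusted over the list alone; adjusted p = 0.493), 3 and 6 with scaling on arthropod hits, and 1 and 2 without that library. Egg formation had 3 rises and 2 falls of 11 (3 and 2 adjusted over the list alone; adjusted p = 0.356), 1 and 2 without that library, and storage proteins 3 falls and 1 rise of 9 (1 and 4 adjusted over the list alone; adjusted p = 0.701), 1 and 1 of 11 without that library. Hexamerin 1 (13_Contig_210), a storage protein of insect blood, had a log2 change of -3.76 ± 0.98 that was -1.20 and did not pass without that library.

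The largest falls of the comparison were mostly unigenes with protist or other non-arthropod hits. Of the 8 named, 7 were of this kind and lost their call without mature larva replicate 1. For example, a U5 snRNP protein (13_Contig_39776) averaged 51.8 ± 89.5 CPM in the mature larvae and had no subimago read, at least 2274-fold less. Its log2 change without that library was -5.33. The exception was apolipoprotein D (13_Contig_3452), a lipid carrier with 2 subimago reads, for a ratio of 12339 (95% interval 3416 to 101888), and it was called without that library as well, though its log2 change of -13.37 ± 2.11 was then -9.84.

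edgeR called 3064 unigenes higher and 4833 lower in the subimago than in the mature larva, and 1964 and 1831 with an arthropod hit. The total of 7897 was 3090 without mature larva replicate 1 (1042 higher, 2048 lower), 3069, 1850 and 2118 without subimago replicates 1, 2 and 3, and 10808 at the highest when a library was left out. The share called higher was 38.8%, 59.9% with library totals alone, 27.5% with scaling on arthropod hits, 24.3% without mature larva replicate 2 and 18.6% with a fold of at least 2. The median shift in log2 change was 0.27 with library totals and -0.18 with arthropod scaling. Camera called 3 lists upwards and 6 downwards, but 5 upwards and 3 downwards without mature larva replicate 1. Its calls of muscle, digestive enzymes, glycolysis and DNA replication were lost there (adjusted p = 0.572, 0.231, 0.808 and 0.0820), and chitin and chemoreception passed upwards (adjusted p = 0.0417 and 0.0381). The remaining new upward call was the algal and plant list, which reached 5 tested unigenes without that library. With 1 other library left out, muscle, DNA replication, heat shock proteins, glycolysis and photoreception were lost in 4, 4, 4, 2 and 1 of 5 fits (adjusted p up to 0.492, 0.166, 0.341, 0.145 and 0.0831). With the stricter filter camera lost DNA replication and heat shock proteins (adjusted p = 0.271 and 0.0820). It then called detoxification and ion transport downwards (adjusted p = 0.00899 and 0.00140). With 1 unigene per annotation text camera lost digestive enzymes (adjusted p = 0.208) and called chitin upwards (adjusted p = 0.0361).

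The comparison of imago with subimago covers the moult between the winged stages. Most cuticular proteins fell. Cuticle protein 19 (13_Contig_301) fell from 58.6 ± 4.03 CPM to a single read in the 3 imago libraries, a ratio of 8843 (95% interval 1587 to 349266). ACP-20 (13_Contig_25170) fell from 969.8 ± 330.5 to 0.305 ± 0.0135 CPM (log2 change -11.62 ± 1.07, adjusted p = 5.16e-05, n = 3) and CPR67Bc (13_Contig_1860) from 394 ± 72.0 to 0.174 ± 0.0676 CPM. Of 32 cuticular proteins, 26 fell and 1 rose (1 and 28 adjusted over the list alone), with a median log2 change of -5.74 (adjusted p = 4.93e-21 by camera and adjusted p = 0.228 with an estimated correlation). Osiris 7 (13_Contig_655), of a family of membrane proteins of insect epithelia, fell from 3552 ± 1579 to 1.61 ± 0.606 CPM and the chitin-binding peritrophin 13_Contig_4094 from 179 ± 16.3 to 0.0923 ± 0.0384 CPM. A further cuticular protein (13_Contig_4884) and a seminal fluid protein (13_Contig_9399) had log2 changes of -9.06 ± 0.90 and -8.91 ± 1.38.

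Of 67 chitin and tanning unigenes, 22 fell and 2 rose (4 and 23 adjusted over the list alone; adjusted p = 0.000329 by camera and adjusted p = 0.638 with an estimated correlation). Chitin synthases 13_Contig_2861 and 13_Contig_3176, which polymerise chitin, fell from 119 ± 35.9 to 5.11 ± 1.23 CPM and from 137 ± 32.9 to 4.66 ± 0.374 CPM, and a chitinase (13_Contig_1449) fell from 272 ± 63.5 to 21.2 ± 2.39 CPM. Of 106 ribosomal proteins, 46 fell and 60 did not pass (0 and 49 adjusted over the list alone; adjusted p = 0.00169 by camera and adjusted p = 0.768 with an estimated correlation; unadjusted, 1 higher and 50 lower), for example L5 (13_Contig_5366), from 114 ± 11.1 to 18.8 ± 1.07 CPM. More genes of replication rose than fell. Of 41 members, 9 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 3.00e-05 by camera and adjusted p = 0.638 with an estimated correlation), and ribonucleotide reductase (13_Contig_8070), which makes DNA precursors, rose from 27.5 ± 5.82 to 98.2 ± 3.73 CPM. Of 68 heat shock proteins and chaperones, 13 rose and 5 fell (17 and 5 adjusted over the list alone; adjusted p = 0.0308 by camera and adjusted p = 0.718 with an estimated correlation), while chaperonin subunit epsilon (13_Contig_830) fell from 192 ± 11.5 to 107 ± 12.2 CPM. Of 33 wing patterning unigenes, 5 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.0177 by camera and adjusted p = 0.638 with an estimated correlation), with vestigial (13_Contig_18470), a wing selector gene, rising from 5.27 ± 0.460 to 18.1 ± 3.63 CPM.

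The largest rises were a takeout protein (13_Contig_8287), from 1.93 ± 0.931 to 230.3 ± 49.5 CPM, a chemosensory-binding protein (13_Contig_7993), from 2.80 ± 1.81 to 278 ± 64.2 CPM, and a serine/threonine kinase (13_Contig_6396), from 2.32 ± 1.93 to 164 ± 63.8 CPM. The call of 13_Contig_8287 was lost under 7 settings, with adjusted p up to 0.0969. Heat shock protein 67B2 (13_Contig_10003) had a log2 change of 4.88 ± 0.71. Homogentisate 1,2-dioxygenase (13_Contig_8067) and 4-hydroxyphenylpyruvate dioxygenase (13_Contig_4912), enzymes that break down tyrosine, rose from 0.468 ± 0.0851 to 22.2 ± 3.47 CPM and from 0.752 ± 0.132 to 17.3 ± 1.09 CPM. Prophenoloxidase subunit 2 (13_Contig_5595), the zymogen of a melanin-forming enzyme, rose from 1.00 ± 0.0700 to 25.2 ± 8.76 CPM and a putative acetylcholinesterase (First_Contig179) from 1.12 ± 0.0986 to 29.9 ± 8.28 CPM.

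In lists that camera did not call, detoxification had 15 rises and 7 falls of 135 (17 and 8 adjusted over the list alone; adjusted p = 0.372), with cytochrome P450 13_Contig_11610 rising from 0.983 ± 0.171 to 13.7 ± 0.455 CPM. Digestive enzymes had 26 falls and 12 rises of 201 (13 and 26 adjusted over the list alone; adjusted p = 0.795), with trypsin-7 (13_Contig_2864) falling by a log2 change of -2.49 ± 0.20. Fatty acid metabolism had 8 rises and 5 falls of 53 (8 and 6 adjusted over the list alone; adjusted p = 0.308), with a fatty acyl-CoA reductase (13_Contig_6103) falling from 109 ± 26.8 to 6.36 ± 1.23 CPM and an elongase (13_Contig_11268) rising from 3.06 ± 0.513 to 35.9 ± 1.08 CPM. Oxidative phosphorylation had 10 falls and 2 rises of 71 (2 and 11 adjusted over the list alone; adjusted p = 0.795), and glycolysis 6 rises and 5 falls of 55 (7 and 6 adjusted over the list alone; adjusted p = 0.991), 6 and 8 with arthropod scaling. Photoreception had 9 falls and 2 rises of 33 (3 and 10 adjusted over the list alone; adjusted p = 0.262). Chemoreception had 4 falls and 1 rise of 23 (1 and 4 adjusted over the list alone; adjusted p = 0.277), and immune response 7 falls and 1 rise of 49 (1 and 7 adjusted over the list alone; adjusted p = 0.178). Ion transport had 13 falls and 8 rises of 82 (10 and 14 adjusted over the list alone; adjusted p = 0.782), 12 and 14 with DESeq2's size factors. Egg formation had 3 rises and 1 fall of 11 (3 and 1 adjusted over the list alone; adjusted p = 0.0935), with bicaudal C (13_Contig_854) rising from 784 ± 245 to 2207 ± 108 CPM. In muscle structure 1 rose and 1 fell of 47 (adjusted p = 0.681; 3 and 1 with DESeq2's size factors, 0 and 1 with arthropod scaling), in sperm and axoneme 2 of 22 rose (adjusted p = 0.795) and in storage proteins 1 of 9 fell (adjusted p = 0.426). Of these lists, adjusted over the list alone, the 2 sperm and axoneme rises passed and the others did not.

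edgeR called 2300 unigenes higher and 3161 lower in the imago than in the subimago, 1626 and 1314 of them with an arthropod hit. The total of 5461 was 3010 without subimago replicate 1, 3176, 3532 and 3227 without imago replicates 1, 2 and 3, and 8944 in a fit to only these 6 libraries. The share called higher was 42.1%, 52.6% with library totals, 54.8% with DESeq2's size factors, 54.9% with DESeq2, 56.3% with the stricter filter, 58.9% among arthropod hits fitted on their own and 31.2% with a fold of at least 2. The median shift in log2 change was 0.15 with library totals and 0.12 with DESeq2's size factors. Camera's call of heat shock proteins was lost in 4 of 6 fits with a library left out (adjusted p up to 0.161), and that of wing patterning with the stricter filter (adjusted p = 0.271).

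**Figure D4:**
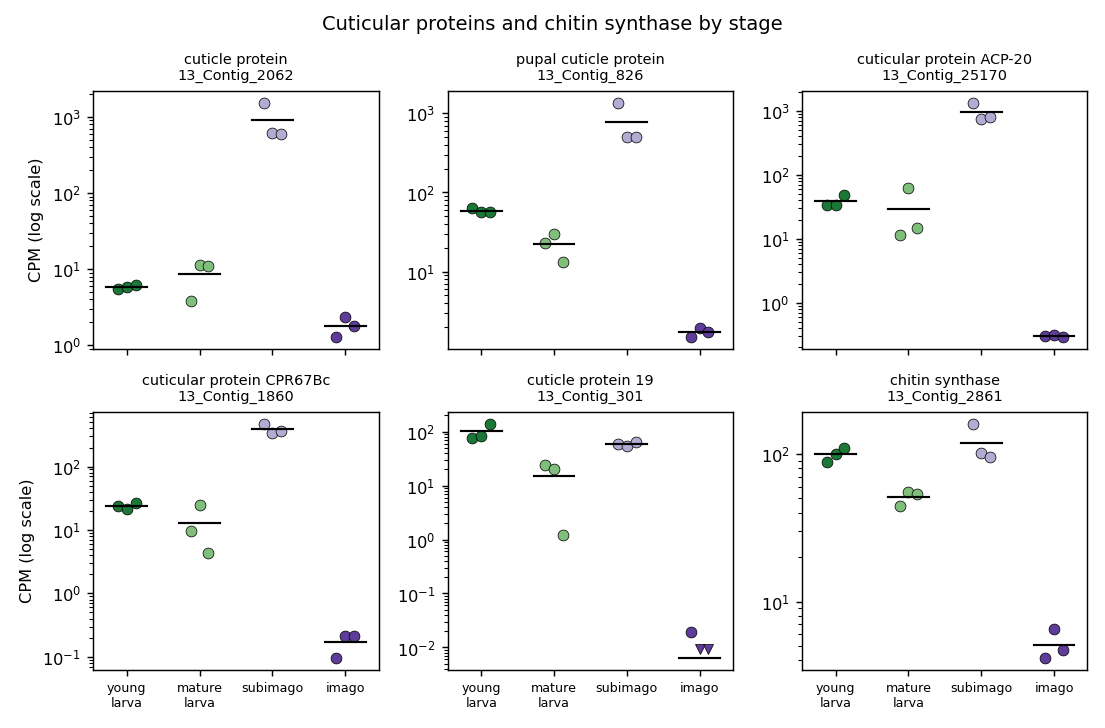
Levels of 5 cuticular proteins and a chitin synthase in CPM on a log scale (y axis) in the 4 stages (x axis); points are libraries, horizontal lines are stage means, and triangles stand for libraries without a read, drawn at 0.5 times the lowest value above 0. The cuticle protein 13_Contig_2062 averages 8.74 ± 4.23 CPM in the mature larva, 919 ± 542 in the subimago and 1.80 ± 0.537 in the imago.

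Hormone genes were followed over all 3 transitions, since ecdysteroids and juvenile hormone time insect moults. Ecdysone 20-monooxygenase (13_Contig_3366), the enzyme that activates ecdysone, rose from 0.0943 ± 0.0613 to 83.1 ± 29.1 CPM from young to mature larva (log2 change 9.69 ± 0.42, adjusted p = 2.99e-09) and stood at 130.1 ± 12.9 CPM in the subimago and 159.8 ± 9.66 in the imago, where its changes did not pass. Unigenes whose best hits were Broad-complex, a transcription factor of metamorphosis, moved apart, and isoform names here are those of the best hits. Isoforms 1/2/3/4/5 (13_Contig_5238) rose from 37.9 ± 1.72 to 121 ± 17.0 CPM and isoform 6 (13_Contig_1375) from 20.9 ± 3.31 to 236 ± 85.5 CPM from young to mature larva, while isoform Z3 (13_Contig_15337) fell from 199 ± 15.0 to 45.2 ± 35.2 CPM and isoform Z1 (13_Contig_3631) from 83.5 ± 6.50 to 22.0 ± 15.8 CPM. Without mature larva replicate 1 the log2 changes of Z3 and Z1 were -2.89 and -2.57. Isoform 6 then fell from 236 ± 85.5 to 60.6 ± 17.4 CPM from mature larva to subimago (log2 change -1.96 ± 0.32, adjusted p = 0.00328). The nuclear receptor HR3 (13_Contig_1820), an ecdysone response gene, stood at 740.0 ± 459.6 CPM in the mature larva and fell from 301 ± 43.2 to 32.0 ± 4.01 CPM from subimago to imago (log2 change -3.23 ± 0.57, adjusted p = 0.00250). The receptor FTZ-F1 (13_Contig_7794) varied between mature larva libraries (277 ± 370.3 CPM), and its rise from young to mature larva (log2 change 2.48 ± 0.78, adjusted p = 0.0265) was lost under 8 settings, with adjusted p up to 0.356. Among 22 ecdysteroid unigenes, 10 rose and 4 fell from young to mature larva (11 and 5 adjusted over the list alone; 5 and 5 with library totals). In the subimago 3 rose and 6 fell (3 and 6 adjusted over the list alone; 4 and 4 with library totals), and 2 rose and 2 fell in the imago (2 and 4 adjusted over the list alone; 2 and 3 with arthropod scaling). Without mature larva replicate 1 the first 2 transitions had 11 rises and 5 falls, and 3 falls. Camera called none of them (adjusted p = 0.264, 0.697 and 0.535).

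Juvenile hormone acid methyltransferase (13_Contig_6017), a late enzyme of the hormone's synthesis, rose from 0.486 ± 0.170 to 4.41 ± 2.14 CPM from young to mature larva. Juvenile hormone epoxide hydrolase 1 (13_Contig_8447), which degrades the hormone, fell from 31.2 ± 10.3 to 8.65 ± 3.10 CPM. A putative farnesoic acid O-methyltransferase (13_Contig_3744) fell from 112 ± 15.3 to 61.0 ± 4.83 CPM, fell again to 38.3 ± 4.22 in the subimago and rose to 86.7 ± 6.39 CPM in the imago (log2 change 1.18 ± 0.12, adjusted p = 8.54e-05). Methoprene-tolerant (13_Contig_51), the hormone's receptor, rose from 208 ± 27.8 to 344 ± 20.2 CPM from subimago to imago (log2 change 0.73 ± 0.16, adjusted p = 0.00860; adjusted p up to 0.0546, past 0.05 without subimago replicate 1). Its earlier rise from young to mature larva (log2 change 0.52 ± 0.16) was -0.03 with library totals. Of 19 juvenile hormone unigenes, 3 rose and 6 fell between larvae (3 and 7 adjusted over the list alone). In the next steps 1 rose and 4 fell in the subimago (1 and 4 adjusted over the list alone), and 4 rose and 3 fell in the imago (5 and 3 adjusted over the list alone), with camera's adjusted p at 0.0698, 0.674 and 0.175. Without mature larva replicate 1 the first had 3 rises and 9 falls of 20 and the second 1 and 4. With TMM scaling none of the 5 moulting and eclosion neuropeptide unigenes was called by edgeR at any transition (camera's adjusted p = 0.426, 0.0764 and 0.362). At an unadjusted p under 0.05, 2 were lower in the mature larva and 2 higher in the subimago, and DESeq2 called 2 lower and 1 higher at these steps. Between larvae edgeR called 1 lower with DESeq2's size factors, 2 with library totals and 2 with arthropod scaling. With mature larva replicate 1 left out, edgeR called 1 lower in the mature larva, eclosion hormone, and none in the subimago. This gene (13_Contig_3138), which triggers ecdysis behaviour, stood at 2.70 ± 0.723, 1.62 ± 0.489, 2.76 ± 0.199 and 1.94 ± 0.246 CPM from young larva to imago.

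**Figure D5:**
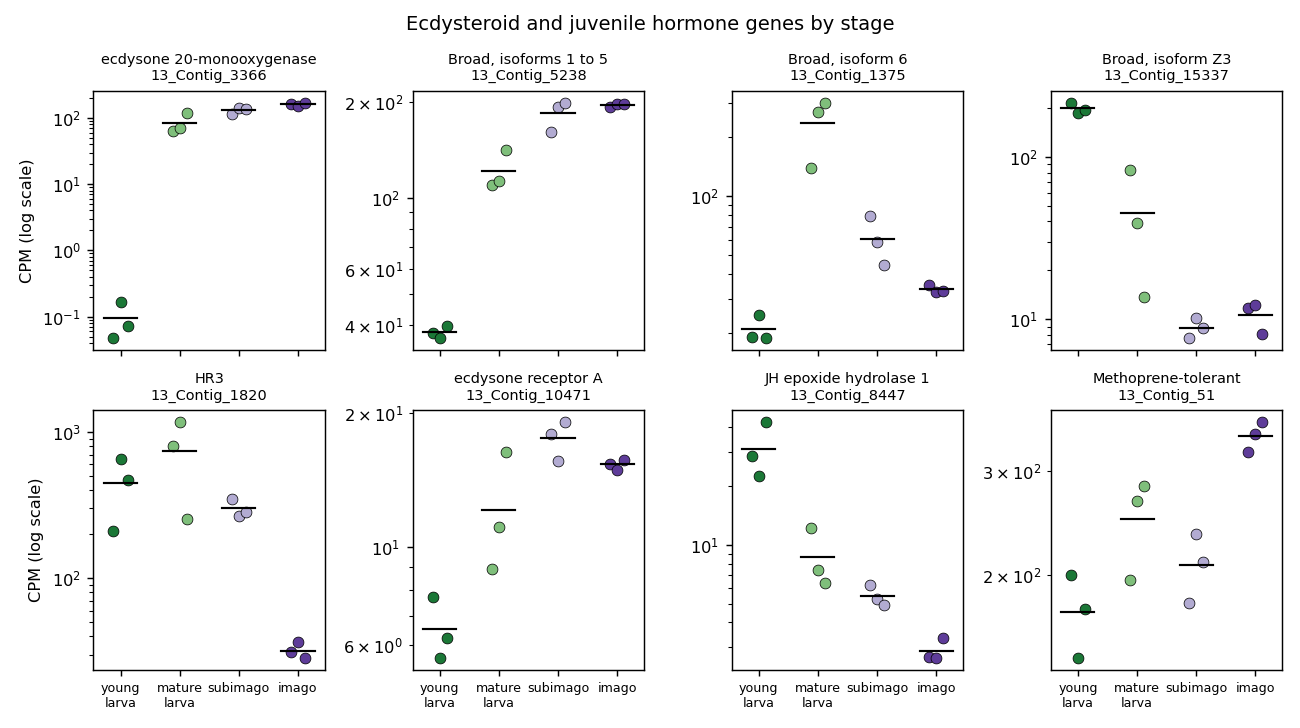
Levels of 8 ecdysteroid and juvenile hormone unigenes in CPM on a log scale (y axis) in the 4 stages (x axis); points are libraries and horizontal lines are stage means. Ecdysone 20-monooxygenase averages 0.0943 ± 0.0613 CPM in the young larva and 83.1 ± 29.1 in the mature larva, and HR3 averages 301 ± 43.2 in the subimago and 32.0 ± 4.01 in the imago.

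The subimago was also compared with both of its neighbours. Unigenes higher there than in mature larva and imago included the cuticle proteins 13_Contig_2062, 13_Contig_826, 13_Contig_25170 and 13_Contig_1860, the chitinase 13_Contig_1449, trypsin-7 (13_Contig_2864), the aromatic-L-amino-acid decarboxylase 13_Contig_1393, the odorant receptor 13_Contig_2497 and chemosensory protein 2 (13_Contig_5261). The latter stood at 17.1 ± 5.73, 69.4 ± 13.7 and 12.2 ± 0.842 CPM in mature larva, subimago and imago. Unigenes lower there than in both included vestigial (13_Contig_18470), at 12.0 ± 2.34, 5.27 ± 0.460 and 18.1 ± 3.63 CPM, and the farnesoic acid O-methyltransferase 13_Contig_3744. In all, 724 unigenes were higher and 408 lower than in both neighbours, where independent lists of these sizes would share 283.8 and 325.7. The contrasts share the subimago libraries, which enter them with opposite sign, so independent lists do not measure chance here. In 10 simulations without differences, edgeR called no unigene at either transition, so none of either kind could arise. At an unadjusted p under 0.05 the means were 113 higher and 243.1 lower. Against these, 1.2 rose and 2.6 fell at both transitions. These unadjusted means cannot be set against the 724 and 408, which were called at an adjusted p. Without subimago replicates 1, 2 and 3 the counts were 347, 380 and 353 higher and 256, 185 and 216 lower, against 69.1, 46.3 and 55.2 and 46.2, 38.9 and 67.6 for independent lists of these fits. They were 494 and 309 without mature larva replicate 1. Without imago replicates 1, 2 and 3 the lower count was 262, 253 and 252. Beside them, 186 unigenes rose and 375 fell at both transitions, against 206.5 and 447.6 for independent lists, a comparison with the same limit.

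The mixture pooled 5 young larvae among 11 animals, but the 1244 unigenes named above as read in every young larva but not in the later stages, mature larva replicate 1 aside, stood at 0.132%, 0.195% and 0.160% of their young larva level in its replicates. The 63 of them with an arthropod hit stood at 0.274%, 0.262% and 0.177%. The comparisons below are with these pools as sequenced. Against the mixture the young larvae stood apart most. Ribosomal protein genes were higher in them, with 94 of 106 higher and 3 lower (94 and 3 adjusted over the list alone), for example 40S protein SA (13_Contig_12463, log2 difference 2.40 ± 0.20). Of 47 muscle unigenes 30 were higher and 3 lower (30 and 3 adjusted over the list alone), with myosin heavy chain (Second_Contig9) at 4.85 ± 0.68. Of 201 digestive enzymes 112 were higher and 34 lower (116 and 35 adjusted over the list alone). Of 41 DNA replication unigenes 32 were lower and 7 higher (33 and 7 adjusted over the list alone), and of 11 egg formation unigenes 7 were lower and 1 higher, with vitellogenin (13_Contig_814) at -12.06 ± 0.54. edgeR called 9523 unigenes higher and 9948 lower, among them 2066 protist hits that were higher. The share called higher was 48.9%, 64.0% with library totals and 38% without mixture replicate 1. The median shift in log2 difference was 0.55 with library totals, 0.24 with DESeq2's size factors and 0.38 with arthropod scaling.

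edgeR called few unigenes between the mature larva or the subimago and the mixture. At an unadjusted p under 0.05, 7893 and 5670 of 34131 differed, so the few calls do not show that few unigenes differed. In the mature larvae 46 of 106 ribosomal proteins were higher (81 higher and 3 lower adjusted over the list alone), such as L5 (13_Contig_5366, log2 difference 1.19 ± 0.17), and the cuticle protein 13_Contig_2062 was lower (-4.19 ± 0.77). Of all unigenes 120 were higher and 254 lower (32.1% higher). Their sum of 374 was 5 in a fit to only these 6 libraries, all lower, and 38 with library totals (2.63% higher). It was 4538 with DESeq2 (62.3% higher), and 52.1% were higher with arthropod scaling, where the median shift was 0.15. The share was 50.2% without a filter, 53.6% with the stricter filter, 17.4% with a fold of at least 2 and 14.7% without mixture replicate 1. Without mature larva replicates 1, 2 and 3 the sum was 384, 111 and 1813, and without mixture replicate 1 it was 68. In the subimagoes 8 of 201 digestive enzymes were lower and 5 of 68 heat shock proteins higher against 1 lower (2 and 16, and 9 and 1, higher and lower adjusted over the list alone). The tyrosine enzyme homogentisate 1,2-dioxygenase (13_Contig_8067) was lower (-4.95 ± 0.39). Of all unigenes 201 were higher and 581 lower, and their sum of 782 was 29 with library totals and 3863 with DESeq2. Without subimago replicates 1, 2 and 3 the sum was 185, 84 and 132, and without mixture replicates 1 and 2 it was 260 and 167. The share called higher was 25.7%, against 49.0% with DESeq2's size factors, 53.4% with DESeq2 37.7% with arthropod scaling, 40.7% among arthropod hits fitted on their own, 37.3% with the stricter filter and 36.8% in a fit to only these 6 libraries. It was 8.17% with a fold of at least 2, 11.4% and 3.57% without subimago replicates 1 and 2, and 8.08% and 7.19% without mixture replicates 1 and 2. The median shift was 0.31 with library totals.

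In the imagoes cuticle genes were lower than in the mixture, with 23 of 32 cuticular proteins lower (27 lower and 1 higher adjusted over the list alone) and CPR67Bc (13_Contig_1860) at a log2 difference of -9.80 ± 0.97. Of 67 chitin and tanning unigenes 24 were lower (24 adjusted over the list alone), with chitin synthase 13_Contig_2861 at -3.81 ± 0.25, and of 106 ribosomal proteins 54 were lower and 1 higher (57 and 1 adjusted over the list alone). Of 68 heat shock proteins 22 were higher and 1 lower (29 and 3 adjusted over the list alone), and 9 of 41 DNA replication unigenes were higher (18 adjusted over the list alone). edgeR called 1782 unigenes higher and 3921 lower, and the sum of 5703 was 2133, 2544 and 2026 without imago replicates 1, 2 and 3, 2445 without mixture replicate 2 and 10877 with DESeq2. The share called higher was 31.2%, 72.8% with library totals, 58.6% with DESeq2's size factors, 58.1% with DESeq2, 52.6% with the stricter filter and 55.5% among arthropod hits fitted on their own. It was 7.15% with a fold of at least 2, 8.44%, 11.4% and 9.82% without imago replicates 1, 2 and 3, and 6.18% without mixture replicate 2. The median shift was 0.46 with library totals, 0.19 with DESeq2's size factors and -0.13 with arthropod scaling.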

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

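The scaling on arthropod hits, the fits to arthropod hits alone and without First_Contig81, and the lists limited to animal hits were chosen after the results were seen. Counts of called unigenes moved by more than 1.5 times as follows, and the cause was not tested. A fit to only the libraries compared gave 7772 unigenes between the larval stages, 3920 for subimago against mature larva, 8944 for imago against subimago and 5 for mature larva against mixture. Library totals alone gave 38 for mature larva against mixture, 29 for subimago against mixture and 225 lower in the subimago than in both neighbours. Without a filter, 3290 were called for subimago against mature larva, and 424 were higher and 240 lower in the subimago than in both neighbours. The strict filter, with fewer unigenes tested, gave 7520, 4790, 9335, 819 and 3731 for mature against young larva, subimago against mature larva, and young larva, mature larva and imago against the mixture, with 322 higher in the subimago than in both neighbours. A fold of at least 2 gave 236 and 3679 for mature larva and imago against the mixture. DESeq2 gave 12122 for subimago against mature larva, 4538, 3863 and 10877 for mature larva, subimago and imago against the mixture, and 820 lower in the subimago than in both neighbours. Arthropod scaling gave 1258 for subimago against mixture. Arthropod hits alone gave 6816, 4496, 8307 and 950 for mature against young larva, subimago against mature larva, and young and mature larva against the mixture, with 368 higher in the subimago than in both neighbours. With an estimated correlation 0 lists were called at each transition, where fry called 18, 7 and 6.

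Leaving out 1 library gave 9713 to 19551 unigenes for mature against young larva, 1850 to 10808 for subimago against mature larva and 3010 to 4618 for imago against subimago. Against the mixture it gave 15115 to 20337 for the young larva, 68 to 1813 for the mature larva, 84 to 904 for the subimago and 2026 to 5790 for the imago. The subimago had 347 to 846 unigenes higher and 185 to 445 lower than in both neighbours, and 12 to 13, 5 to 9 and 5 to 6 lists were called. Methoprene-tolerant (13_Contig_51) reversed with library totals between the larval stages (log2 change -0.0287). FTZ-F1 (13_Contig_7794) from mature larva to subimago ran from -0.74 without mature larva replicate 2 to 1.92 without replicate 3, where it reversed, and photoreception reversed with fry between the larval stages (adjusted p = 0.0118). Of 2058 results for named unigenes with a library left out, 1846 were the same, 192 no longer passed and 19 newly passed. The planned other pseudocount had no use with counts and was not run.

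Between mature and young larvae, deviations of libraries with the same replicate number correlated at 0.548, 0.572 and -0.247 for replicates 1, 2 and 3. For replicates 1 and 2 the library of the same number was the best match. In the other comparisons the values ran from -0.117 to 0.134, so the numbers did not pair the libraries there. With the replicate number as a block, 239 unigenes were called for mature larva against mixture, and 12540, 5350 and 5056 at the 3 transitions. In the simulations 2-fold changes were recovered at 3% to 7%, so most changes of that size were missed there. Since few unigenes were changed in them, these rates do not measure recovery in the real comparisons.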

Other observations

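The tests of young larva replicate 1 alone, of another organism, of First_Contig81 and of protist hits, and the regroupings of libraries, were chosen after the results were seen. For a young larva mixture and for depth, the predictions were written before their tests were run.

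Tyrosine breakdown is a family chosen after its values were seen and not tested as a list. Of its 7 unigenes, 4 fell from young to mature larva, 5 fell in the subimago and 4 rose in the imago, and without mature larva replicate 1 the first 2 counts were 6 and 4. Homogentisate 1,2-dioxygenase (13_Contig_8067) had log2 changes of -1.89 ± 0.34, -4.25 ± 0.38 and 5.56 ± 0.41, and tyrosine aminotransferase (13_Contig_6703), the first enzyme of the pathway, -0.92 ± 0.18, -2.27 ± 0.18 and 3.30 ± 0.19. Both tested Osiris unigenes fell from subimago to imago, Osiris 16 (13_Contig_16540) with a log2 change of -6.32 ± 1.57. Of 21 yellow family members, which act in pigmentation, 2 rose and 8 fell between larvae, 2 rose and 5 fell in the subimago, and 2 fell in the imago. Of the yellow members 2 rose and 13 fell between larvae without mature larva replicate 1, and 2 rose and 1 fell in the subimago.

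Of 733 tested unigenes without a young larva read, 191 stood at 10 CPM or more in all 9 later-stage libraries. Of these 15 had an arthropod hit and 166 had no protein hit. A non-negative fit of stage means to the mixture, over 7122 arthropod-hit unigenes, put mixture replicate 1 at 51.3% subimago and 38.7% imago, replicate 2 at 60.5% subimago, and replicate 3 at 64.7% mature larva. The young larva shares were 5.39%, 8.79% and 0%, where 5 of the 11 animals were young larvae by the labels. The 1244 unigenes named above as read in young larvae stood at 0.132%, 0.195% and 0.160% of their young larva level in these replicates. The 63 of them with an arthropod hit stood at 0.274%, 0.262% and 0.177%. These levels are far below the fitted shares of replicates 1 and 2. The fit's mature larva mean included mature larva replicate 1. The amount of RNA per animal is not given in the sources used here.

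Mature larva replicate 1 lay between the young larvae and the other mature larvae. Depth as the cause is argued against, since thinned to the depth of the shallowest mature larva library it still held reads of 1.5 times as many unigenes as the higher of the others. Another organism alone is argued against too, as on arthropod-hit unigenes it lay 0.599 of the way to the young larvae. For young larva RNA or reads mixed into replicate 1 in general, the lists' median shares of the young larva level differed by 1.94 times, short of the bound of 2 set beforehand against it but too far apart to speak for it, so that test decides nothing. Set against young larva replicate 1 alone, a test added after that value was seen, they differed by 1.2 times. Over the 1244 unigenes named above, log2 reads correlated at 0.942, 0.715 and 0.828 with young larva replicates 1, 2 and 3. As 642 of these had a protist hit and 63 an arthropod hit, the correlations do not describe mayfly RNA alone. Unigenes without a young larva read, which mixing would dilute, stood at 69.5% of replicates 2 and 3, but at 98.6% by library totals. Replicate 2 itself stood at 69.6% and 52.5% of replicate 3 on these scales, so dilution cannot be told. RNA or reads of young larva replicate 1 may be the source, while younger animals in the pool stay open and untested.

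First_Contig81 took a large part of the reads of some libraries. Its level differed 9024-fold between imago libraries, which argues against a mayfly transcript set by stage. Whether several unigenes are pieces of 1 RNA cannot be told, as over the 5 libraries with at least 1000 CPM of it the ratios of 3 short unigenes to it varied by 3.79%, 17.1% and 35.3%, the last from as few as 2 reads. What the RNA is stays open, and no biological explanation was tested.

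Unigenes with a protist best hit were high in young larvae and in mature larva replicate 1. For mayfly transcripts with a chance protist hit, arthropod-hit unigenes kept 16.3 times the share of their young larva level in the mixture that protist-hit unigenes kept. Among unigenes of young larvae without a read in the later stages, mature larva replicate 1 aside, the ratio was 1.93. This was a ratio of summed levels rather than of medians, from 110 mixture reads of 63 arthropod-hit and 143 of 642 protist-hit unigenes. With so few reads this stays open. For RNA of another organism in the sample, young larva replicate 2 held arthropod-hit unigenes at 2.23 times the relative level of protist-hit ones. Among the 63 and 642 unigenes just named the value was 0.801. Their choice by no read in the later stages may itself make the 2 kinds alike, so this stays open too. Diet or gut content of the animals stays open and was not tested.

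The 3 transitions and the comparisons with the mixture allow 10 splits of 6 libraries each, too few to exclude chance. Fits to those 6 libraries called 7772, 3920 and 8944 unigenes at the transitions and 17720, 576 and 6556 for young larva, subimago and imago against the mixture, where 1 split, the real one, gave as many and the highest other gave 0. For mature larva against the mixture the real split gave 5, the highest other 90, and 2 splits gave as many. The gene lists called were 15, 9 and 5, against 13, 14 and 6 for the highest other split, and 1, 6 and 3 splits gave as many. For unigenes higher in the subimago than in both neighbours, 4 of 60 groupings of the 9 libraries gave as many as the real 767 (highest other 1348). For unigenes lower there, 2 of 60 gave as many as the real 505 (highest other 1796). All 56 groupings that mixed stages in the middle gave 0, and those with more unigenes put another stage in the middle, a structure of the samples, so these shares do not test chance.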
